A study of Mus musculus with 419 samples.

How the data were processed

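RNA was measured by bulk sequencing in 419 libraries from 19 tissues of CBA/CaJ mice, with the sexes, Control and Deficient treatments and the collection times ZT05 and ZT17 taken from the deposited labels. Per the labels, total RNA was extracted with TRIzol and 500 ng entered stranded poly(A) library construction (TruSeq Stranded mRNA). The authors deposited raw read counts per gene; the labels list FastQC 0.11.9, cutadapt 4.1, STAR 2.7.10a and DESeq2 1.34.0 with the GRCm38 (mm10) build, and state neither the counting tool nor the annotation release. The deposited counts were whole numbers whose library totals differed, so they were used without rescaling. A second deposited table held the same counts multiplied by 1 constant per library and was not used. The count table held 55487 genes, of which 248 shared a symbol with another gene, or carried a symbol that had been turned into a date, and were named by their Ensembl identifier. Gene positions were taken from GENCODE release M21 for GRCm38.

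Samples were joined to count columns by the names given in the labels, with 0 columns left over. Those names also carried animal numbers: the 12 females and 12 males numbered 31 to 62 are called the first cohort, and 12 males numbered 73 to 94 the second cohort. Replicate numbers did not pair libraries within a tissue, since the mean correlation of residuals between libraries with the same number lay between -0.021 and 0.1. Levels of sex-specific genes contradicted the labelled sex in 0 libraries.

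Each tissue was fitted alone with edgeR 4.0.16 in R 4.3.3. Genes passed edgeR's default expression filter (minimum count 10, minimum total count 15), libraries were scaled by TMM, and a negative binomial quasi-likelihood model held 1 coefficient per group of sex, treatment and time. The responses of females and of males were Deficient minus Control, averaged over both times. The sex difference was the female minus the male response. The time difference was the response at ZT17 minus the response at ZT05, averaged over the sexes present. ZT17 minus ZT05 was also tested within Control and within Deficient mice. Quasi-likelihood F tests were adjusted by the Benjamini-Hochberg procedure over the genes tested in the tissue, and genes with adjusted p under 0.05 are called changed. Numbers of called genes are also given as percent of the genes tested in that fit, and for sums as percent of the gene and tissue pairs tested, of the genes tested in 5 or more tissues, or of the list tests. The same denominator is kept under each alternative, and counts were compared as counts. Log2 fold changes are given with their standard error from the same model. Levels (CPM) are on TMM-scaled library sizes, given as mean and SD over the libraries of an arm, 6 in each arm except 5 for Control males in the tendon of the tibialis anterior. The labels allow the sexes of a tissue to differ in cohort, and all 7 tissues with only second-cohort males confound sex with cohort.

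Gene lists were written from general knowledge of each process or cell type, 74 in all with 5 to 74 members. Of 1666 members written, 1656 matched a symbol in the count table. Lists with at least 5 tested members were compared with the other genes of the tissue by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data. The p-values of camera were adjusted over all tissues and lists of a contrast, 1193 tests in females and 1129 in males. Members called changed were also counted with p-values adjusted over the list alone. A shared response was a gene called in the same direction in 5 or more tissues, a minimum set after the data had been seen, as was the choice of which lists the text describes.

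The tests, lists, panels and rule for naming genes were fixed before the data were examined. Named genes were, per tissue and sex, the 3 largest rises and the 3 largest falls among changed genes with a mean of at least 8 CPM, passing over predicted genes, clone names and immunoglobulin or T cell receptor segments. They were joined by the 10 genes called up and the 10 called down in most tissues per sex, up to 4 called members of each described list with the largest change and every called member going against it, the 2 largest differences per tissue for the sex and time differences, and a panel of known genes per tissue. The text names part of the panels and part of the genes each rule selects. Some genes that these rules select are not reported here. Differences between times for 20 clock genes were tabulated in every tissue.

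Alternatives chosen with the plan were DESeq2's size factors in edgeR, no low-count filter, a stricter filter (5 CPM in at least 3 libraries), DESeq2 1.42.0, the replicate number as a further term, the libraries of a single sex, a term for library cohort, each library left out in turn, an estimated inter-gene correlation, and the sex difference over heart, lung and pituitary, whose male libraries all had first-cohort animal numbers and library names of the earlier form. Alternatives chosen after seeing the data were removal of mitochondrially encoded and rRNA-like genes, removal of libraries with over 50% of their counts in those genes, and limma voom with sample quality weights. Treatment labels were exchanged within sex and time in 30 splits per tissue, and time labels in 21, the real split included and the same exchange made in every tissue. Random splits were drawn with fixed seeds.

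The tests were tried on simulated data made from the fitted means and dispersions of each tissue, with 200 changed genes. The shared fit recovered a median of 64.2% of female and 65.7% of male changes of 1 on the log2 scale, 97% and 93.9% of changes of 2, and 6.75% and 13.4% of changes of 0.5. False calls numbered 0 to 53 in females and 2 to 199 in males, and 2 to 14 and 0 to 12 when the libraries of a single sex were fitted. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No library was left out of the main comparisons.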

Results

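Poly(A) RNA was counted in 419 libraries from 19 tissues of CBA/CaJ mice, used to model REDs (relative energy deficiency in sport). Energy-sufficient (Control) and energy-deficient (Deficient) mice of both sexes were sampled at zeitgeber times 5 h (ZT05) and 17 h (ZT17). The tissues were adrenal gland, brown adipose tissue (BAT), heart, kidney, liver, lung, pituitary, spleen, ovary, uterus, testis, the extensor digitorum longus (EDL), gastrocnemius, quadriceps, soleus and tibialis anterior (TA) muscles, and the tendons of the EDL, gastrocnemius and TA. Both sexes were sampled in 16 tissues. Each of 140 groups of sex, treatment, time and tissue held 3 libraries, except that 1, the TA tendon of Control males at ZT05, held 2. Each comparison within a sex therefore set 6 Deficient against 6 Control libraries, or 5 Control libraries in the male TA tendon. Library totals ran from 5777450 to 53598697 counts. Mitochondrially encoded and rRNA-like genes took over 50% of the counts in 58 libraries, each from a first-cohort male. Outside these genes, male BAT libraries kept as few as 376712 counts and male liver libraries 496991 to 1527111.

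**Figure D1:**
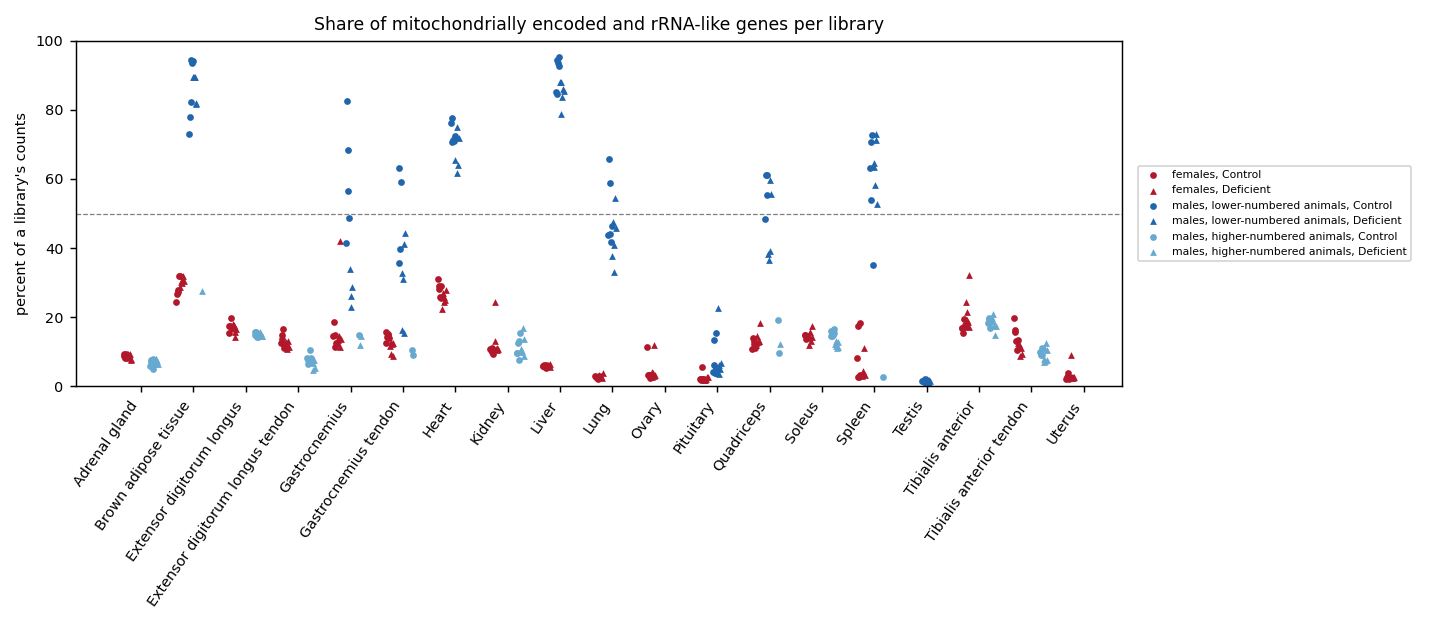
Percent of each library's counts in mitochondrially encoded and rRNA-like genes, with 1 point per library by tissue, sex, treatment and animal numbering. The 58 libraries above the dashed 50% line all come from males of the lower-numbered cohort.

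The first comparison asked which genes responded to energy deficiency in each tissue and sex. Over 18 female tissues, 14524 gene and tissue pairs rose and 15588 fell in Deficient mice. Over 17 male tissues, 8603 pairs rose and 8803 fell. Uterus changed most, with 3766 genes up and 4221 down, followed by male kidney with 3370 up and 3489 down. Each sex fitted alone gave 40858 pairs in females and 11777 in males, so counts depended on which libraries shared the fit. In the 9 tissues with first-cohort males, male dispersion was 1.2 to 7.27 times the female one. The shared fit holds 1 estimate of the spread for both sexes. Leaving out single libraries moved 35.4% of 587 recomputed counts by more than 1.5-fold. Between 13406 and 20816 genes were tested per tissue, and smaller sets of called genes are given below as percent of these.

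**Figure D2:**
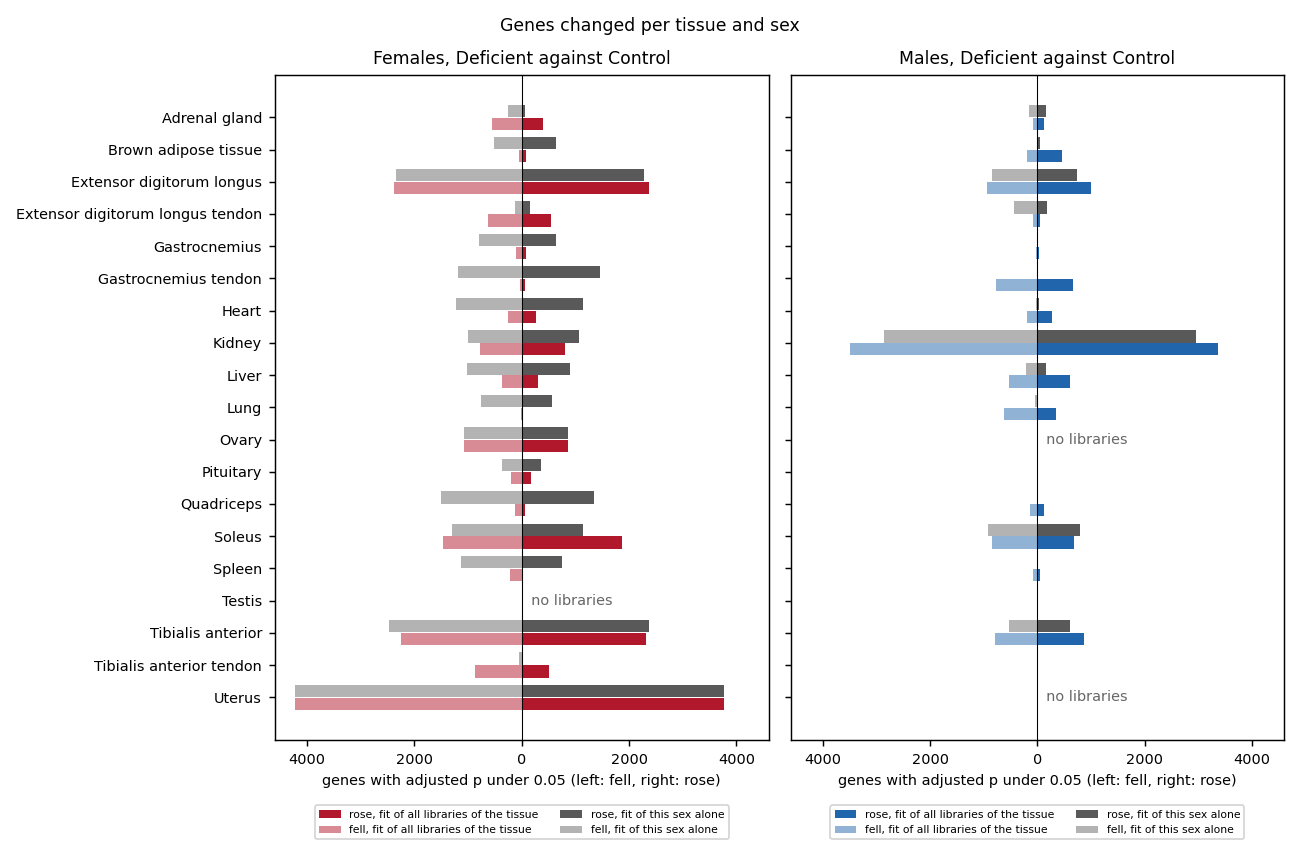
Number of genes with edgeR adjusted p under 0.05 that rose (right) or fell (left) in Deficient mice, per tissue and sex, in the fit of all libraries of a tissue and in the fit of a single sex. Uterus (3766 up, 4221 down) and male kidney (3370 up, 3489 down) show the longest bars.

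Some responses recurred across organs, but tissues shared mice (12 females gave all 18 female tissues) and were not independent. Of 18202 genes tested in 5 or more female tissues, 2.68% rose and 2.93% fell in at least 5; of 17724 tested in as many male tissues, 0.655% rose and 0.553% fell. The cold-inducible RNA-binding protein gene Cirbp (ENSMUSG00000045193; chromosome 10, 80165985 to 80172786, GRCm38) rose in 16 of 18 female tissues, with a median log2 fold change of 1.07. Cbx7 rose in 14 female tissues, and the glucocorticoid target Fkbp5 (ENSMUSG00000024222; chromosome 17, 28399094 to 28517527) in 13 female tissues, with a median of 1.29, and in 11 male tissues. Per1 and Jade2 also rose in 13 female tissues. Among males, Prodh rose in 10 tissues and Zbtb16 and Cdkn1a in 9. The collagen chaperone gene Serpinh1 (ENSMUSG00000070436; chromosome 7, 99345376 to 99353239) fell in 15 of 18 female tissues with a median of -1.12. Nrep fell in 13 female tissues, and Col3a1 and the haemoglobin gene Hbb-bs in 12. Ccnd1 fell in 11 of 17 male tissues, and Aplnr, Col1a1, Nrep and Col1a2 in 10. Glucocorticoid-responsive genes had a positive median in 17 of 18 female and 17 of 17 male tissues and were called up by camera in 15 and 14, but with an estimated correlation in 2 and 0. Collagens and extracellular matrix genes were called down in 15 female and 12 male tissues, and with an estimated correlation in 4 and 1.

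**Figure D3:**
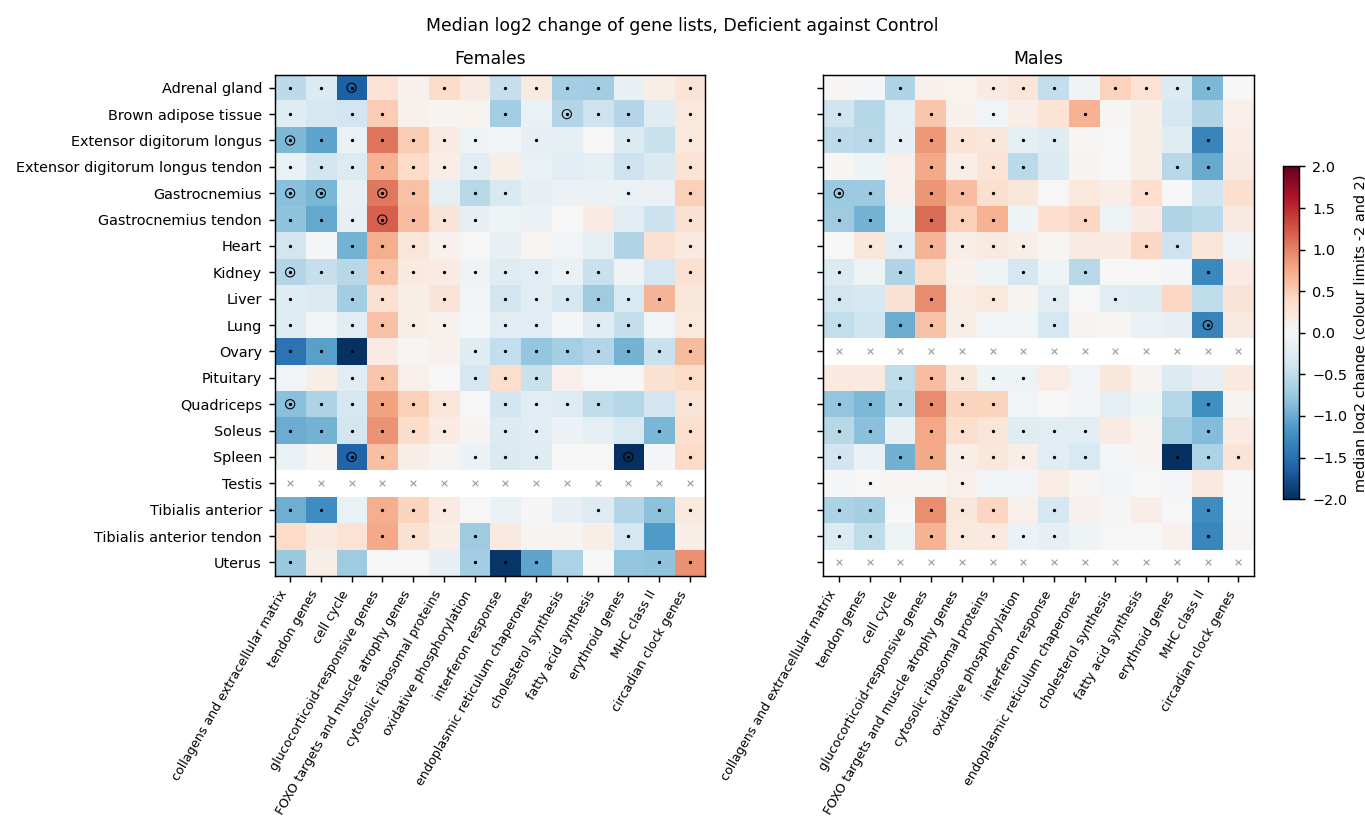
Median log2 fold change of gene lists (columns) in each tissue (lines of the grid) for Deficient against Control females and males; dots mark camera adjusted p under 0.05 and circles the calls that held with an estimated correlation. Glucocorticoid-responsive genes are positive in 17 of 18 female and 17 of 17 male tissues, and crosses mark tissues without libraries.

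Among reproductive organs, uterus changed most. There, the epithelial gene Aoc1 (ENSMUSG00000029811; chromosome 6, 48872896 to 48909188) fell from 544 ± 457 CPM (SD, n = 6) to 2.16 ± 2.49 (n = 6), a log2 fold change of -8.50 ± 0.92 (SE; adjusted p = 0.000224). The oestrogen-regulated genes Ltf (-4.93 ± 0.79, adjusted p = 0.000638), Lcn2 (-5.87 ± 0.81) and Sprr2f (-6.01 ± 1.02) fell as well, while Bpifb5 (7.74 ± 0.71), Slc5a11 (7.36 ± 0.87) and Cxcl15 (6.99 ± 0.93) rose. Of 32 oestrogen and progesterone responsive uterine genes, 15 fell and 5 rose, or 16 and 5 when adjusted over the list alone (camera adjusted p = 0.00657; adjusted p = 0.464 with an estimated correlation). Oviduct and endometrial epithelium markers fell in 8 of 14 cases and rose in 3 (9 and 3 adjusted over the list alone; camera adjusted p = 0.0293, and 0.704 with an estimated correlation). The 5 hormone-responsive genes that rose were Ihh, Hand2, Lrp2, Cyp26a1 and Scnn1a. Esr1 (0.05 ± 0.16) and Mki67 (0.06 ± 0.49) did not pass (adjusted p = 0.832 and 0.935), and Pgr gave 0.68 ± 0.30 (adjusted p = 0.0823). Interferon-response genes fell in 34 of 38 cases (34 adjusted over the list alone; camera adjusted p = 6.44e-22, and 0.441 with an estimated correlation), led by Zbp1 (-4.13 ± 0.56) and Oas3 (-3.86 ± 0.55). Markers of neutrophils fell in 9 of 11 cases and those of macrophages and monocytes in 15 of 20, while endothelial markers rose in 12 of 16 cases and fell in 1 (10, 16 and 12 adjusted over the list alone; camera adjusted p = 0.000432, 9.06e-06 and 0.000536, and 0.524, 0.441 and 0.518 with an estimated correlation). T and NK cell markers went both ways (3 up and 3 down; camera adjusted p = 0.503). Endoplasmic reticulum chaperones fell in 21 of 23 cases (21 adjusted over the list alone), with Sdf2l1 at -2.24 ± 0.39 (camera adjusted p = 9.08e-12, and 0.441 with an estimated correlation).

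Ovary gave 865 rises and 1077 falls. Npbwr1 (ENSMUSG00000033774; chromosome 1, 5913707 to 5917398) rose by 2.58 ± 0.35 (adjusted p = 0.00729), and Cyp2a5 by 2.04 ± 0.45. The largest falls among genes of at least 8 CPM were those of Clca1 (-4.85 ± 1.33), Aqp8 (-4.05 ± 1.08) and Mki67 (-3.80 ± 1.07, adjusted p = 0.0479). Col1a1 dropped from 323.5 ± 144.3 to 45.4 ± 25.7 CPM (n = 6 each), a log2 fold change of -2.91 ± 0.36 (adjusted p = 0.006). Of 44 matrix genes 27 fell (35 adjusted over the list alone; camera adjusted p = 4.93e-29, and 0.176 with an estimated correlation). Markers of some other cell types were lower too: smooth muscle genes in 14 of 14 cases, adipocyte markers in 22 of 22, macrophage and monocyte markers in 20 of 21 and endothelial markers in 14 of 16 (8, 3, 8 and 1 called, and 12, 4, 8 and 9 adjusted over the list alone; camera adjusted p = 1.37e-09, 1.58e-05, 1.49e-05 and 0.000852, and 0.265, 0.71, 0.513 and 0.664 with an estimated correlation). Ciliated cell markers were higher in 15 of 15 cases, with none called (camera adjusted p = 0.000865, and 0.79 with an estimated correlation). Cell-cycle genes fell in 14 of 43 cases (34 adjusted over the list alone; camera adjusted p = 1.21e-13, and 0.652 with an estimated correlation). Cyp19a1 (-5.78 ± 2.29, adjusted p = 0.135), Lhcgr (-7.43 ± 2.97) and Star (-1.47 ± 1.03) did not pass. Camera called the lists of steroid synthesis, granulosa and luteal genes down (adjusted p = 0.0397, 0.0293 and 0.00657, and 0.83, 0.841 and 0.737 with an estimated correlation), with 1 of 22, 0 of 18 and 2 of 23 genes called down (edgeR; 0, 0 and 3 adjusted over the list alone). In testis 2 genes rose, Dcn (0.69 ± 0.10, adjusted p = 0.0107) and Mro (0.40 ± 0.07, adjusted p = 0.0492), and 4 fell. The 4, named after their values had been seen, were Klk1b21 (-3.07 ± 0.34), Klk1b27 (-2.98 ± 0.41), Klk1b24 (-2.80 ± 0.33) and Gprc5a (-1.14 ± 0.19), whereas Star (-0.95 ± 0.23) and Cyp17a1 (-0.92 ± 0.32) did not pass (adjusted p = 0.144 and 0.262).

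In pituitary, 0.904% of the genes tested rose and 1.03% fell in females. Gal (ENSMUSG00000024907; chromosome 19, 3409915 to 3414544) fell from 303.8 ± 160.7 to 34.6 ± 21.5 CPM (n = 6 each), a log2 fold change of -3.12 ± 0.64 (adjusted p = 0.0136). Oxidative phosphorylation genes fell in 4 of 49 cases (10 adjusted over the list alone), with Ndufa1 at -0.74 ± 0.14 (camera adjusted p = 1.93e-12, and 0.44 with an estimated correlation). The hormone genes Prl (-1.03 ± 0.33, adjusted p = 0.124), Gh (-0.22 ± 0.26) and Pomc (0.52 ± 0.63) did not pass in females. In males edgeR called 0 genes, against 11.7% of the genes tested at unadjusted p under 0.05 and 0.729% by DESeq2.

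In liver, sex-biased genes changed in both sexes. The male-biased gene Hsd3b5 (ENSMUSG00000038092; chromosome 3, 98618634 to 98630252) fell from 31.3 ± 15.4 to 0.296 ± 0.267 CPM in males (n = 6 each; log2 -6.67 ± 0.73, adjusted p = 1.43e-06) and from 6.16 ± 5.81 to 0.124 ± 0.124 CPM in females (log2 -5.30 ± 0.48, adjusted p = 6.43e-08). Male-biased liver genes fell in 23 of 28 cases in each sex, or 26 in females and 25 in males when adjusted over the list alone. These list calls held with an estimated correlation (camera adjusted p = 0.0123 in females and 0.036 in males). Mup7 fell by 5.35 ± 0.38 in females, and Mup16 (-9.29 ± 0.95) and Elovl3 (-5.17 ± 0.77) fell in males. Female-biased genes rose in 19 of 30 cases in females, while A1bg and Ntrk2 fell (22 up and 3 down adjusted over the list alone; adjusted p = 0.0327 with an estimated correlation). In males 11 of 30 rose (12 adjusted over the list alone; camera adjusted p = 4.26e-10, and 0.0893 with an estimated correlation). Cux2 (ENSMUSG00000042589; chromosome 5, 121856366 to 122050102) rose by 2.49 ± 0.49 in females and 5.90 ± 1.13 in males. Fatty acid synthesis genes fell in 10 of 25 cases in females (15 adjusted over the list alone), with Scd1 dropping from 3682 ± 910.1 to 1062 ± 460.1 CPM (camera adjusted p = 4.57e-13, and 0.176 with an estimated correlation). In male liver the arms differed in library composition: mitochondrially encoded genes took 84.85 ± 7.53% of counts in Control and 66.04 ± 23.26% in Deficient libraries (n = 6 each), and the median of counts outside these and rRNA-like genes was 2.17 times as high in Deficient ones. Genes of gluconeogenesis and amino acid breakdown rose in 15 of 30 cases in males and Otc fell (22 up and 1 down adjusted over the list alone), with G6pc at 1.92 ± 0.41 (camera adjusted p = 1.76e-11, and 0.112 with an estimated correlation). Igf1 fell in males (-0.70 ± 0.18, adjusted p = 0.0171, and 0.062 with males fitted alone) and gave -0.45 ± 0.18 in females (adjusted p = 0.181). Igfbp1 rose in males by 2.75 ± 0.75 (adjusted p = 0.0212), and Fgf21 fell in females by 2.75 ± 0.54 from a mean of 0.542 CPM.

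In 5 limb muscles of both sexes, camera called matrix genes down and glucocorticoid-responsive genes and atrophy genes up in 10 of 10 comparisons, but with an estimated correlation in 4, 1 and 0 (lowest adjusted p for atrophy genes 0.176). The EDL had 2377 rises and 2377 falls in females and 994 and 934 in males, and TA and soleus followed (2323 and 2242, and 1875 and 1464, in females). Col1a1 (ENSMUSG00000001506; chromosome 11, 94936224 to 94953042) fell in EDL from 125.9 ± 39.8 to 20.1 ± 6.01 CPM in females (n = 6 each; log2 -2.63 ± 0.23, adjusted p = 1.72e-07) and from 151.2 ± 44 to 26.3 ± 11.2 CPM in males (log2 -2.58 ± 0.23, adjusted p = 8.12e-07). Col1a1 also fell in female soleus (-2.26 ± 0.27) and TA (-2.53 ± 0.28) and in male gastrocnemius (-2.34 ± 0.26) and quadriceps (-2.20 ± 0.32; adjusted p = 0.101 with males fitted alone). In female EDL 33 of 44 matrix genes fell (35 adjusted over the list alone). This held with an estimated correlation (camera adjusted p = 0.0435). So did the falls in female quadriceps (0.0292) and gastrocnemius of males (0.036) and females (0.0152, and of tendon genes 0.0296). The ubiquitin ligase gene Fbxo32 (ENSMUSG00000022358; chromosome 15, 58175879 to 58214932) rose in EDL by 1.92 ± 0.19 in females and 1.20 ± 0.19 in males, and Trim63 by 1.39 ± 0.23 and 0.68 ± 0.23. Of 33 FOXO targets and muscle atrophy genes 26 rose in female EDL (26 adjusted over the list alone; camera adjusted p = 5.85e-15, and 0.176 with an estimated correlation). Cytosolic ribosomal protein genes rose slightly, in 67 of 73 cases in male TA (71 adjusted over the list alone; median 0.43, camera adjusted p = 2.25e-41, and 0.386 with an estimated correlation). Igf1 fell in TA of females (-1.05 ± 0.15) and males (-1.11 ± 0.19). Actc1 fell in female TA (-2.65 ± 0.36), gastrocnemius (-2.60 ± 0.52) and quadriceps (-2.79 ± 0.57). The rRNA-like transcript CT010467.1 and Lars2 were also called up in female TA, with Deficient SDs above their means (33100 ± 79000 and 3040 ± 7160 CPM). Male gastrocnemius and quadriceps gave 64 and 264 genes in the shared fit, but 10 and 0 with males fitted alone (1026 at unadjusted p under 0.05 in quadriceps, and 754 by DESeq2 in the shared fit).

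In heart, 1.68% of the genes tested rose and 1.62% fell in females, and 1.65% and 1.21% in males. Map3k6 rose in females from 3.13 ± 1.37 to 10.2 ± 3.31 CPM (n = 6 each; log2 1.79 ± 0.26, adjusted p = 0.000748) and in males by 1.65 ± 0.27. Proliferation genes fell in females, with Mki67 at -2.73 ± 0.48, and 10 of 42 cell-cycle genes passed (21 adjusted over the list alone; camera adjusted p = 4.72e-18, and 0.176 with an estimated correlation). In males the endothelial gene Aplnr fell by 2.90 ± 0.42, and 9 of 12 neutrophil markers rose, including Chil3 by 6.44 ± 1.53 (12 adjusted over the list alone; camera adjusted p = 2.93e-13, and 0.277 with an estimated correlation). With males fitted alone 1 of these markers passed. Myh7 rose in females by 0.83 ± 0.20, whereas Nppa (0.29 ± 0.35) and Nppb (-0.03 ± 0.24) did not pass.

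In BAT the thyroid hormone activating gene Dio2 (ENSMUSG00000007682; chromosome 12, 90724552 to 90738438) rose in females from 37.8 ± 39.5 to 183.3 ± 129.2 CPM (n = 6 each; log2 3.37 ± 0.46, adjusted p = 0.000283) and in males by 2.60 ± 0.54. Cyp2b10 rose by 3.15 ± 0.40 in females and 5.76 ± 0.55 in males. Ucp1 did not pass, at -0.15 ± 0.30 in females (adjusted p = 0.944) and -0.17 ± 0.30 in males (adjusted p = 0.793). Cholesterol synthesis genes fell in 7 of 25 cases in females (1 up and 14 down adjusted over the list alone), with Insig1 at -1.94 ± 0.25, and this list call held with an estimated correlation (adjusted p = 0.0296). Endoplasmic reticulum chaperones rose in 10 of 23 cases in males, led by Dnajb9 (1.55 ± 0.30), but 0 passed with males fitted alone (13 adjusted over the list alone in the shared fit; camera adjusted p = 5.51e-09, and 0.385 with an estimated correlation). Mitochondrially encoded genes took 81.53 ± 10.68% of counts in male Control and 65.34 ± 28.36% in Deficient libraries.

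Adrenal glands of females lost proliferation genes. Mki67 (ENSMUSG00000031004; chromosome 7, 135689784 to 135716361) fell from 18.7 ± 6.49 to 2.41 ± 1.41 CPM (n = 6 each; log2 -2.92 ± 0.36, adjusted p = 5.85e-05), and 36 of 43 cell-cycle genes fell (38 adjusted over the list alone; camera adjusted p = 0.000334 with an estimated correlation). Scd1 fell from 4424 ± 1377 to 640.8 ± 285.4 CPM. The corticotropin receptor gene Mc2r rose by 0.50 ± 0.09 (adjusted p = 0.00325, and 0.0517 with females fitted alone), while Star (-0.13 ± 0.15), Cyp11b1 (0.15 ± 0.15) and Cyp11b2 (-0.88 ± 0.35) did not pass. The 2 largest rises, Cyp2a5 (9.15 ± 2.14) and Dnase1 (8.68 ± 2.34), had Deficient SDs above their means, and did not pass with females fitted alone (adjusted p = 0.114 and 0.157). Of 13 kidney tubule markers 7 rose (11 adjusted over the list alone, and 0 with females fitted alone; camera adjusted p = 0.000696, and 0.705 with an estimated correlation). In males, adipocyte genes rose: Retn (ENSMUSG00000012705; chromosome 8, 3655770 to 3660110) went from 11.6 ± 3.74 to 83.3 ± 28.3 CPM (log2 2.84 ± 0.28, adjusted p = 1.86e-05), Cfd rose by 2.94 ± 0.35 and Adipoq by 2.18 ± 0.25. Of 22 adipocyte markers 11 rose (16 adjusted over the list alone; camera adjusted p = 0.036 with an estimated correlation).

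Of male tissues, kidney changed most. Prlr (ENSMUSG00000005268; chromosome 15, 10177238 to 10349180) rose from 1.49 ± 0.756 to 24.7 ± 10.7 CPM in males (n = 6 each; log2 4.04 ± 0.31, adjusted p = 1.97e-08), Ugt1a2 by 7.62 ± 0.85 and Cyp4a14 by 4.81 ± 0.63, while Angptl7 (-3.65 ± 0.35) and the androgen-metabolism gene Srd5a2 (-3.47 ± 0.35) fell. Oxidative phosphorylation genes fell in 43 of 49 cases in males (46 adjusted over the list alone), with Cycs at -0.99 ± 0.14 (camera adjusted p = 1.81e-15, and 0.574 with an estimated correlation). In females Fn1 fell from 104.1 ± 18.2 to 30.9 ± 6.16 CPM. Of 44 matrix genes 26 fell in females while Lox and Ctgf rose (29 down and 2 up adjusted over the list alone; adjusted p = 0.0238 with an estimated correlation). The vitamin D activating gene Cyp27b1 (ENSMUSG00000006724; chromosome 10, 127048250 to 127053006) rose by 1.97 ± 0.30 in females and 0.89 ± 0.29 in males.

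In lung, Hif3a (ENSMUSG00000004328; chromosome 7, 17031507 to 17062427) rose from 2.33 ± 1.27 to 10.4 ± 4.75 CPM in females (n = 6 each; log2 2.30 ± 0.39, adjusted p = 0.0251) and by 2.80 ± 0.41 in males. In males H2-Ob (-3.04 ± 0.47), Ccl5 (-2.43 ± 0.40) and Cr2 (-2.80 ± 0.60; adjusted p = 0.11 with males fitted alone) fell. All 11 MHC class II genes fell (11 adjusted over the list alone, and 6 with males fitted alone), and the list call held with an estimated correlation (adjusted p = 0.036). B cell markers fell in 16 of 19 cases and T and NK cell markers in 20 of 24 (18 and 24 adjusted over the list alone; camera adjusted p = 7.05e-21 and 2.25e-29, and 0.316 and 0.224 with an estimated correlation). With males fitted alone 2 of each list passed.

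Spleen lost erythroid transcripts. Alas2 (ENSMUSG00000025270; chromosome X, 150547375 to 150570638) fell from 164.9 ± 132.3 to 8.691 ± 4.123 CPM in females (n = 6 each; log2 -4.26 ± 0.54, adjusted p = 0.000126) and from 148.1 ± 82.3 to 9.563 ± 5.716 CPM in males (log2 -3.87 ± 0.55, adjusted p = 0.0049). In females 22 of 25 erythroid genes and 32 of 43 cell-cycle genes fell (25 and 43 adjusted over the list alone), and both calls held with an estimated correlation (camera adjusted p = 0.0152 and 0.0292). In males 13 erythroid genes fell (21 adjusted over the list alone; camera adjusted p = 1.38e-29, and 0.277 with an estimated correlation). With males fitted alone 11 passed, among 19 genes in all. Mitochondrially encoded genes took 39.95 ± 24.03% of counts in male Control and 54.35 ± 11.39% in Deficient libraries, and 4 of 30 splits of the labels gave at least as many genes in the shared fit.

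**Figure D4:**
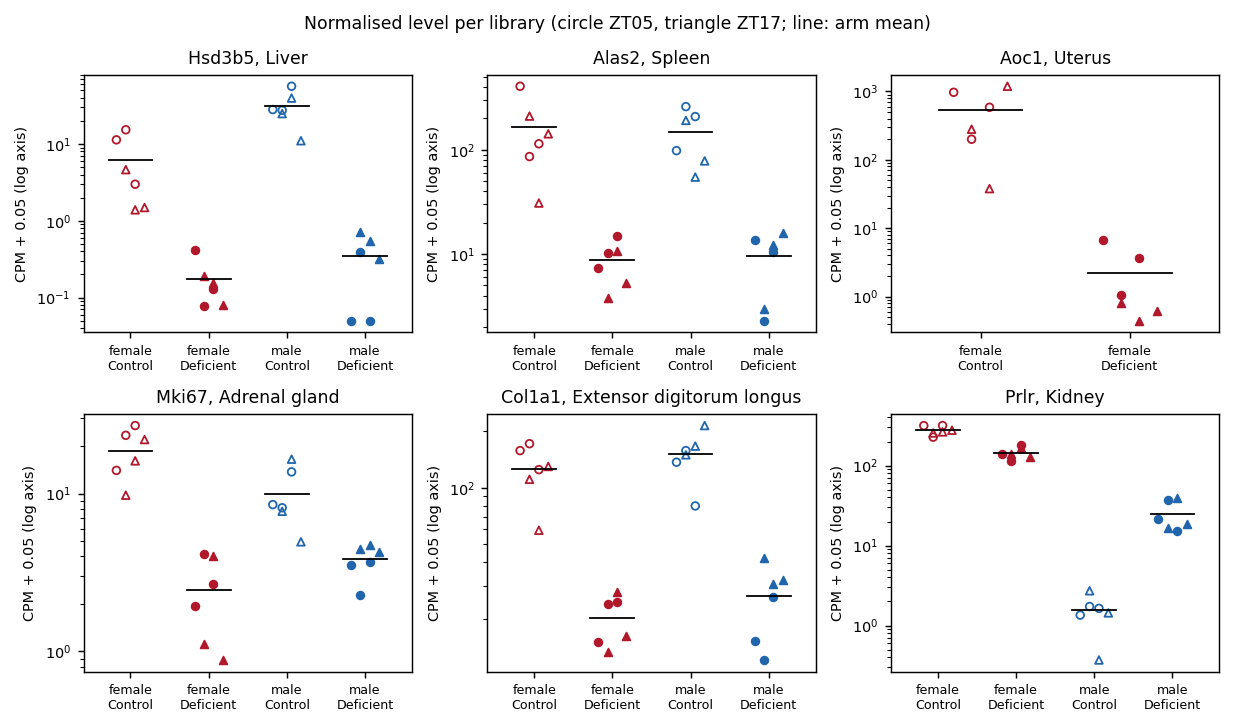
CPM plus 0.05 on a log axis for 6 named genes, with 1 point per library, circles for ZT05, triangles for ZT17 and a line at each arm's mean. Deficient means are lower for Hsd3b5, Alas2, Aoc1, Mki67 and Col1a1 in each sex sampled, while Prlr fell in female and rose in male kidney.

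In tendons, Col1a1 fell in females in the gastrocnemius tendon (-2.28 ± 0.45) and in the EDL tendon, from 1382 ± 621.6 to 299.6 ± 145.4 CPM (n = 6 each; log2 -2.25 ± 0.35, adjusted p = 0.00146). Arrdc2 rose in the EDL tendon by 1.76 ± 0.30 in females and 1.69 ± 0.30 in males, and Fkbp5 in the male EDL tendon by 1.43 ± 0.22 and in the female TA tendon by 1.17 ± 0.28. The tendon markers Tnmd (-0.77 ± 0.44) and Scx (-0.70 ± 0.23) did not pass in the female EDL tendon. Glucocorticoid-responsive genes rose in 7 of 27 cases in the female gastrocnemius tendon (17 adjusted over the list alone), a call that held with an estimated correlation (camera adjusted p = 0.0296). In the female TA tendon 33 of 49 oxidative phosphorylation genes fell (48 adjusted over the list alone), led by Cycs (-1.07 ± 0.23), but 0 passed with females fitted alone (camera adjusted p = 1.7e-26, and 0.441 with an estimated correlation). In the male gastrocnemius tendon 15 of 17 hepatocyte markers rose (16 adjusted over the list alone), such as Apoa1 at 9.88 ± 2.65. In 1 Deficient library they summed to 65540 CPM, in the rest to at most 468.7. Camera's adjusted p was 2.38e-05, and 0.794 with an estimated correlation. With males fitted alone edgeR called 0 genes in this tendon, against 2113 at unadjusted p under 0.05 and 2333 by DESeq2 in the shared fit. In the male TA tendon edgeR called 0 genes, against 1021 at unadjusted p under 0.05 and 45 by DESeq2.

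Female and male responses were compared. Of pairs called in either sex, 4650 were called in both in the same direction. The difference itself passed for 2962 pairs in 9 of 16 tissues, 2342 of them in kidney. There and in adrenal gland, EDL, soleus and TA sex and cohort coincide. In the other 7 tissues edgeR called 0 genes, against 4.15% to 11.8% of the genes tested at unadjusted p under 0.05 and 0% to 0.95% by DESeq2. In kidney, Prlr fell in females and rose in males, a female minus male difference of -4.97 ± 0.37 (adjusted p = 6.83e-08), and Ugt1a2 differed by -7.83 (adjusted p = 6.11e-05). In liver G6pc fell in females by 1.18 ± 0.31 and rose in males (difference -3.10 ± 0.52), and Cyp2b9 differed by -4.50 ± 0.79. In adrenal gland Retn differed by -3.59 ± 0.38 (adjusted p = 8.29e-05). Lung H2-Ob differed by 3.50 ± 0.61 (adjusted p = 0.0187).

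Collection times were compared to ask whether energy deficiency altered day and night differences. Between ZT17 and ZT05, 16575 gene and tissue pairs differed in Control and 5047 in Deficient mice, and the response differed between times for 5991 pairs in 15 of 19 tissues. Ovary, pituitary, testis and uterus gave 0 genes with edgeR, against 7.09% to 14.7% of the genes tested at unadjusted p under 0.05 and 0% to 2.84% by DESeq2. Among 20 clock genes in 19 tissues, 41.1% of 380 pairs differed between times in Control mice, 31.3% in Deficient mice, and 14.5% between the treatments. Nr1d1 (ENSMUSG00000020889; chromosome 11, 98767932 to 98775333) was lower at ZT17 in 16 Control tissues and in 1 Deficient tissue, and the treatments differed in 14. In liver its ZT17 minus ZT05 difference was -5.76 ± 0.47 in Control and -0.36 ± 0.37 in Deficient mice (difference 5.41 ± 0.62, adjusted p = 2.27e-05). Cry1 was higher at ZT17 in 13 Control and 0 Deficient tissues, with liver values of 3.06 ± 0.31 and 0.05 ± 0.24 (adjusted p = 2.64e-07 and 0.982). Per2 was lower at ZT17 in 9 Deficient tissues and higher in 3 Control tissues, and differed between treatments in 8. Dbp was lower at ZT17 in 15 Control and 14 Deficient tissues, and Arntl higher in 10 and 8. Outside the clock, the response at ZT17 lay below that at ZT05 for Thrsp in liver (-4.16 ± 0.55), Angptl8 in BAT (-5.00 ± 0.56) and Slc25a25 in EDL (-3.67 ± 0.60) and TA (-4.32 ± 0.63).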

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

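The tests of dispersion, depth and opposite phase for the day and night differences and of tissue from another organ in single libraries were chosen only after the result had been seen, and the other tests before. The dispersion test took the place of a test of slopes, the test for single libraries got a condition on abundant genes after a first look, and the organ sums were then changed to counts outside mitochondrially encoded and rRNA-like genes.

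The response differed between females and males by a test of the difference itself (edgeR, adjusted p under 0.05). Values for splits are percent of the genes tested in the tissue, or of the gene and tissue pairs tested. The female minus male differences singled out per tissue were Miox (8.46 ± 2.03, adjusted p = 0.036) and Retn (-3.59 ± 0.38, adjusted p = 8.29e-05) in adrenal gland, Slc5a3 (-3.28 ± 0.58, adjusted p = 0.0182) and Acsl3 (-2.16 ± 0.44, adjusted p = 0.0341) in BAT and Ugt1a2 (-7.83, adjusted p = 6.11e-05) and Prlr (-4.97 ± 0.37, adjusted p = 6.83e-08) in kidney. Others were Cyp2b9 (-4.50 ± 0.79, adjusted p = 0.012) and G6pc (-3.10 ± 0.52, adjusted p = 0.00942) in liver, H2-Ob (3.50 ± 0.61, adjusted p = 0.0187) and Ms4a1 (3.04 ± 0.63, adjusted p = 0.0389) in lung and Dynlrb2 (1.77 ± 0.23, adjusted p = 0.00308) in pituitary. There were also Enho (-1.06 ± 0.20, adjusted p = 0.0375) and Pptc7 (0.92 ± 0.17, adjusted p = 0.0375) in soleus and Pcx (-1.61 ± 0.20, adjusted p = 0.000419) and Gbp10 (1.34 ± 0.26, adjusted p = 0.0483) in TA. Without the adrenal library of Deficient female replicate 1 at ZT17, which held kidney tubule transcripts, Miox gave 3.55 (adjusted p = 0.427). Neither soleus gene passed with DESeq2's size factors, with a replicate term or without mitochondrially encoded and rRNA-like genes. Among 30 splits of the treatment labels the real one gave the most genes. It gave 1.78 against 0.0967 in adrenal gland, 0.232 against 0.0772 in BAT, 13.9 against 9.20 in kidney and 0.731 against 0.0149 in liver. It was 0.788 against 0.410 in lung, 0.0972 against 0 in soleus and 0.0876 against 0.0269 in TA. As many genes came from 2 of 30 splits in EDL (0.0134, highest other 0.383) and 2 of 30 splits in pituitary (0.00517, highest other 0.0103). Beside 0 genes by edgeR, the percents at unadjusted p under 0.05, by DESeq2 and in the highest other split were those of EDL tendon (7.71, 0.0182 and 0.0364), gastrocnemius (6.73, 0.104 and 6.84), gastrocnemius tendon (8.78, 0.239 and 7.25) and heart (11.8, 0.950 and 0.00629). The same held, in this order, for quadriceps (4.15, 0.0192 and 19.7), spleen (10.1, 0.429 and 0.00572) and TA tendon (6.22, 0 and 32.6). Where the real split led, the values ran, across the alternatives and then without single libraries (in brackets, how many moved the count over 1.5-fold), from 1.52 to 19.4 and 0.985 to 3.58 in adrenal gland (7 of 24), 0.161 to 3.15 and 0.0561 to 1.19 in BAT (19 of 24), 12.5 to 18.99 and 9.10 to 17.2 in kidney (1 of 24) and 0.127 to 4.16 and 0.0597 to 1.28 in liver (18 of 24). They ran from 0.0270 to 2.38 and 0.0324 to 2.09 in lung (18 of 24), 0 to 2.33 and 0 to 0.6997 in soleus (22 of 24) and 0.0606 to 5.77 and 0.0135 to 5.38 in TA (22 of 24). Over the 16 tissues 3 of 30 splits gave as many as the 1.15% of pairs, with a highest other of 2.09. As these splits remove the response itself, they cannot test whether it differs by sex or time. A split with several times the real count in a tissue points to a structure of the libraries other than treatment. Sex and cohort coincide in kidney, adrenal gland, EDL, soleus and TA.

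The response also differed between ZT17 and ZT05. Nr1d1, singled out in 12 tissues, responded more positively at ZT17, with differences of 3.28 in EDL, 2.92 in EDL tendon, 3.46 in gastrocnemius, 2.66 in gastrocnemius tendon, 3.46 in heart and 4.20 in kidney. The rest were 5.41 in liver, 3.42 in lung, 3.04 in quadriceps, 3.94 in soleus, 3.40 in TA and 2.88 in TA tendon. Other genes singled out were Hspa1b (-3.42 ± 0.48, adjusted p = 0.006) and Pck1 (3.42 ± 0.76, adjusted p = 0.0475) in adrenal gland, mt-Ti (-5.18 ± 0.81, adjusted p = 0.000244) and Angptl8 (-5.00 ± 0.56, adjusted p = 7.47e-06) in BAT, Slc25a25 (-3.67 ± 0.60, adjusted p = 0.00154) in EDL and Tsc22d3 (-1.80 ± 0.24, adjusted p = 0.00304) in EDL tendon. Further ones were Odf3l2 (-3.36 ± 0.60, adjusted p = 0.0497) in gastrocnemius, Odf3l2 (-4.47 ± 0.52, adjusted p = 0.00049) in gastrocnemius tendon, Per2 (-2.83 ± 0.43, adjusted p = 0.00506) in heart and Mir6236 (-4.30 ± 1.21, adjusted p = 0.0385) in kidney. Next came Thrsp (-4.16 ± 0.55, adjusted p = 5.86e-05) in liver, Retnlg (3.05 ± 0.79, adjusted p = 0.0299) in lung and Otud1 (-4.25 ± 0.75, adjusted p = 0.00316) in soleus. The list ended with Rbm14 (-1.70 ± 0.22, adjusted p = 0.00221) in spleen, Slc25a25 (-4.32 ± 0.63, adjusted p = 0.000823) in TA and Glul (-1.27 ± 0.19, adjusted p = 0.0208) in TA tendon. The real split of treatment labels gave the most genes of 30, with 0.506 against 0 in adrenal gland, 14.5 against 5.03 in BAT, 1.99 against 0.0201 in EDL, 0.107 against 0.00629 in heart and 6.07 against 0.0119 in kidney. It was 3.43 against 1.64 in liver, 6.14 against 0.00540 in lung, 3.86 against 0.00648 in soleus, 0.00572 against 0 in spleen and 1.95 against 0.0135 in TA. At least as many genes came from 2 of 30 splits in EDL tendon (0.0182, highest other 0.206), 3 of 30 splits in gastrocnemius (0.0324, highest other 6.92) and 2 of 30 splits in gastrocnemius tendon (0.0582, highest other 0.524). So did 3 of 30 splits in quadriceps (0.00641, highest other 14.6) and 2 of 30 splits in TA tendon (0.0121, highest other 15.8). With 0 genes by edgeR, the corresponding 3 percents were those of ovary (7.09, 0.349 and 0.343), pituitary (14.7, 2.84 and 0.0568), testis (8.67, 0 and 0) and uterus (8.27, 0.169 and 22.2). In the same form, the values where it led ran from 0.245 to 6.91 and 0.176 to 2.48 in adrenal gland (20 of 24), 12.2 to 19.7 and 10.6 to 21.5 in BAT (0 of 24), 1.83 to 5.29 and 1.34 to 2.18 in EDL (0 of 24), 0.0755 to 3.10 and 0.0314 to 1.49 in heart (19 of 24) and 5.09 to 12.97 and 3.25 to 9.37 in kidney (7 of 24). They ran from 2.17 to 8.01 and 2.16 to 5.04 in liver (2 of 24), 5.04 to 12.5 and 2.79 to 9.96 in lung (15 of 24), 3.30 to 5.85 and 2.31 to 4.01 in soleus (2 of 24), 0 to 0.938 and 0.00572 to 0.944 in spleen (6 of 24) and 1.95 to 5.48 and 1.15 to 4.16 in TA (5 of 24). Over the 19 tissues 1 of 30 splits reached 1.90% of pairs, against a highest other of 1.56.

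Fewer genes differed between ZT17 and ZT05 in Deficient than in Control mice, 5047 against 16575 gene and tissue pairs. Lower depth was argued against by a median Deficient to Control ratio of counts of 1.06 (0.7 to 2.17), and opposite phase by 14.1% of the clock pairs called in Control (22 pairs) with the opposite sign, of which 5 were called, while 75 were called with the same sign. This covers clock genes alone: among all genes called in Control, 60.8% in BAT, 55.7% in lung and 47.5% in liver had the opposite sign in Deficient mice, against 0 to 36.5% in the other 13 tissues with such genes. BAT alone had more genes called in opposite than in the same direction. A reversal outside the clock stayed open in BAT and lung. A larger spread among Deficient libraries stayed open, since the median ratio of dispersions was 1.14 (95% bootstrap interval 0.79 to 1.57) and exceeded 1 in 11 of 19 tissues. A slope of Deficient on Control differences of 0.57 (0.52 to 0.61) did not separate a damped rhythm from noise, as females on males within Control gave 0.61. A phase shift shorter than a reversal or a changed feeding time may also be involved, and neither was tested.

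Markers of other organs were higher in some Deficient libraries. In female adrenal glands 3 of 6 exceeded the highest Control sum of kidney tubule markers (11.15 CPM). In male gastrocnemius tendons 2 of 6 exceeded that of hepatocyte markers. Both argued against a tissue response in all 6 Deficient mice. The tendon of Deficient male replicate 2 at ZT17 held 65540 CPM of hepatocyte markers, 83.25% of the liver sum of 78720 (Spearman rho 0.62 across genes), with Alb at 26540, Hsd3b5 at 49.05 (108.4 in Control and at most 2.32 in Deficient male liver) and Tnnt3 at 10370 (at least 17950 in the other tendons). Liver tissue is thus a candidate explanation there. The adrenal gland of Deficient female replicate 1 at ZT17 held 1797 CPM of kidney markers, 6.31% of the kidney sum of 28470 (rho 0.61), with Umod at 172.9 and Slc34a1 at 426.2. Kidney tissue stayed open there, because Kap lay at 0.2235 against 8447 in Control and 1331 in Deficient kidney; without these libraries 3.34% of genes in adrenal gland and 9.17% in the tendon were called.

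With each sex fitted alone, fewer genes changed in males than in females in the 9 tissues with first-cohort males, while the shared fit gave more male calls in 5 of the 9. Lower depth was argued against: with female counts thinned to the male depth, the female count stayed over 1.5 times the male one in 8 of 9 tissues, from 412 against 52 in BAT to 2247 against 0 in gastrocnemius tendon (edgeR; 2113 at unadjusted p under 0.05), and not in liver (519 against 381). In heart, liver, lung and pituitary both sexes carried first-cohort animal numbers, and cohort could not be tested. In the 5 tissues with both male cohorts, females stayed over 1.5 times the male count after a cohort term entered the male-only fit. The term cannot remove spread, so cohort stayed open. That term raised male counts to 0.995% of genes in that fit in quadriceps, 0.701% in gastrocnemius and 0.937% in BAT. It lowered them from 19 to 9 genes in spleen, and gastrocnemius tendon stayed at 0 by edgeR (14.4% at unadjusted p under 0.05). Male dispersion was 1.2 to 7.27 times the female one in the 9 tissues and 0.32 to 1.17 times in the 7 with only second-cohort males, so the larger spread went with first-cohort males. A biological difference between the sexes and the handling of the male libraries stay open, as neither was tested.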

How the results depend on the processing

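Removal of mitochondrially encoded and rRNA-like genes, removal of libraries with over 50% of counts in them, and voom were chosen only after the data had been seen, and the other alternatives before. Values are percent of the genes tested in the reported fit of a tissue (for sums, of the gene and tissue pairs tested, of the genes tested in 5 or more tissues, or of the list tests). They are called moved when the count behind them differed from the reported count by more than 1.5-fold, and the cause was not tested unless stated.

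DESeq2's size factors and removal of mitochondrially encoded and rRNA-like genes left 44 of 44 counts per sex and over tissues within 1.5-fold. Of 1060 named results 871 passed, of which 620 also passed under each alternative other than leaving out a library, 622 without each library, and 522 in both, and 0 reversed. Calls were lost for 17.5% of the recomputed values with a single sex, 12.8% with voom, 4.15% with a replicate term, 4.99% with a cohort term, 0.794% without a filter, 0.748% with the stricter filter, 0.618% with DESeq2's size factors, 0.709% without mitochondrially encoded and rRNA-like genes, 0.272% with DESeq2 and 6.78% without libraries over 50%. Leaving out a library lost the call for 10.7% of values, in a fit with fewer libraries.

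The share of rises among called genes shifted by over 10 points in few cases. DESeq2's size factors gave 849 up and 1080 down for the time difference in BAT, 1249 and 837 for ZT17 against ZT05 in Control BAT, and 2 and 7 for the time difference in gastrocnemius tendon. Without mitochondrially encoded and rRNA-like genes the splits were 2 and 7 in gastrocnemius tendon and 4 and 8 in heart for the time difference, and 405 and 1131 in female TA tendon. The median of all genes shifted by at most 0.09 and 0.07 under these scalings.

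Of 73 further counts, those of single tissues for the sex and time differences and the day-night contrasts, 4 moved with DESeq2's size factors, 3 without mitochondrially encoded and rRNA-like genes, 12 with a replicate term, 11 with the stricter filter, 50 without a filter, 49 with voom and 57 with DESeq2. Of the 24 recomputed with a cohort term 12 moved, and of the 4 without libraries over 50% 4. The sex difference in soleus fell from 0.0972 to 0 by edgeR with DESeq2's size factors, without mitochondrially encoded and rRNA-like genes and with a replicate term (10.46, 10.4 and 10.3 at unadjusted p under 0.05), and was 1.07 by DESeq2. The size factors and the removal of those genes also both took the day-night contrast in Deficient spleen from 0.0229 to 0.00572 and in Deficient gastrocnemius tendon from 0.0194 to 0.0323, and the size factors the time difference in pituitary from 0 to 0.0672. The replicate term took the sex difference in lung from 0.788 to 0.157.

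With DESeq2, female values rose to 8.46 in adrenal gland, 2.93 in BAT, 11.9 in EDL tendon, 3.57 in gastrocnemius and 3.35 in gastrocnemius tendon. Others were 7.72 in heart, 8.95 in liver, 1.33 in lung and 19.5 in ovary. Further values were 4.84 in pituitary, 3.03 in quadriceps, 2.16 in spleen and 15.2 in TA tendon. Male values rose to 2.84 in adrenal gland, 8.77 in BAT, 6.26 in EDL tendon, 2.08 in gastrocnemius and 15.1 in gastrocnemius tendon. Others were 4.50 in heart, 13.2 in liver, 8.43 in lung and 0.729 in pituitary. Further values were 4.83 in quadriceps, 5.04 in spleen, 0.788 in testis and 0.272 in TA tendon. Sums over tissues rose to 2.38 for the sex difference, 3.61 for the time difference, 3.17 for the day-night contrast in Deficient and 4.56 for genes up in 5 or more tissues in females. Others were 5.15 for genes down in 5 or more tissues in females, 1.52 for genes up in 5 or more tissues in males and 1.56 for genes down in 5 or more tissues in males.

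With voom with sample quality weights, female values rose to 36.1 in adrenal gland, 10.2 in BAT, 12.5 in EDL tendon, 24.7 in gastrocnemius and 20.1 in gastrocnemius tendon. Others were 16.4 in heart, 16.4 in kidney, 20.3 in liver, 13.1 in lung and 39.6 in ovary. Further values were 23.3 in pituitary, 22.9 in quadriceps, 16.2 in spleen and 62.96 in TA tendon. Male values fell to 1.05 in BAT, 0.666 in gastrocnemius tendon, 0.390 in heart, 1.74 in liver, 1.17 in lung and 0 in spleen. Male values rose to 9.32 in adrenal gland, 16.5 in EDL tendon, 3.99 in gastrocnemius and 0.351 in pituitary. Others were 12.7 in quadriceps, 15.6 in soleus, 6.24 in testis and 0.247 in TA tendon. Sums over tissues rose to 5.76 for the sex difference, 5.31 for the time difference and 15.4 for the day-night contrast in Control. Others were 3.13 for the day-night contrast in Deficient, 13.7 for genes up in 5 or more tissues in females and 13.8 for genes down in 5 or more tissues in females. Further values were 1.43 for genes up in 5 or more tissues in males, 1.45 for genes down in 5 or more tissues in males and 2.90 for the overlap of the sexes. Voom's 0 genes in male spleen compare with 0.784 by edgeR and 5.04 by DESeq2.

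With no low-count filter, female values fell to 6.53 in ovary and 5.26 in TA tendon. Female values rose to 3.31 in BAT, 6.35 in heart, 0.491 in lung, 3.60 in quadriceps and 2.99 in spleen. Male values rose to 8.52 in BAT, 2.32 in EDL tendon, 1.67 in gastrocnemius, 6.37 in heart and 0.171 in pituitary. Others were 4.68 in quadriceps, 5.61 in spleen, 1.72 in testis and 0.00603 in TA tendon. Sums over tissues rose to 2.46 for the sex difference, 2.89 for the time difference and 2.91 for the day-night contrast in Deficient. Others were 1.36 for genes up in 5 or more tissues in males and 1.46 for genes down in 5 or more tissues in males.

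With the stricter filter, female values fell to 3.61 in adrenal gland and 0.0648 in lung. Female values rose to 1.002 in gastrocnemius tendon. Male values fell to 0 in testis. Male values rose to 2.08 in EDL tendon and 0.0258 in pituitary. The 0 in testis compares with 0.0288 under the default filter by edgeR and 0.788 by DESeq2, and fewer genes were tested.

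With libraries of a single sex, female values fell to 1.85 in adrenal gland, 1.73 in EDL tendon and 0.380 in TA tendon. Female values rose to 8.13 in BAT, 9.28 in gastrocnemius, 17.1 in gastrocnemius tendon, 14.9 in heart and 14.3 in liver. Others were 7.12 in lung, 3.73 in pituitary, 18.2 in quadriceps and 10.8 in spleen. Male values fell to 0.365 in BAT, 0.0649 in gastrocnemius, 0 in gastrocnemius tendon and 0.327 in heart. Others were 2.84 in liver, 0.291 in lung, 0 in quadriceps and 0.109 in spleen. Male values rose to 1.86 in adrenal gland, 3.67 in EDL tendon, 0.00517 in pituitary and 0.0181 in TA tendon. Sums over tissues fell to 0.192 for genes up in 5 or more tissues in males and 0.180 for genes down in 5 or more tissues in males. Sums over tissues rose to 5.83 for genes up in 5 or more tissues in females and 6.65 for genes down in 5 or more tissues in females. The male 0 values by edgeR compare with 2113 genes (gastrocnemius tendon) and 1026 (quadriceps) at unadjusted p under 0.05 in the same fits, and 15.1 and 4.83 by DESeq2 with both sexes.

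With a cohort term, female values rose to 2.27 in BAT, 5.03 in gastrocnemius, 2.06 in gastrocnemius tendon and 4.86 in quadriceps. Male values rose to 1.55 in gastrocnemius and 6.54 in quadriceps.

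With a replicate term, female values rose to 0.183 in lung. Male values fell to 0.364 in EDL tendon.

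With an estimated inter-gene correlation, camera called 16 lists in females (1.34%), 4 in males (0.354%), and 0 each for the sex and time differences, from 25.9%, 21.9%, 22.3% and 19.6% of list tests. Summed over heart, lung and pituitary, the sex difference was 0.0570% of the pairs of all 16 tissues. Nothing was refitted, so counting fewer tissues forced a lower value and cohort was not tested. Liver was left out for the name of 1 male library. Without libraries over 50% the male gastrocnemius tendon gave 18.5, and this was not run in the other tissues with such libraries, where a group would have kept fewer than 2.

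Each library was left out in turn, which leaves 2 in its group, or 1 in the TA tendon of Control males at ZT05, where the lone library is assumed to vary like the others. Ranges follow, with the value in brackets without each library that moved it, named by arm, time and replicate number. Adrenal gland females ranged from 2.68 to 16.7, moving without Control ZT05 1 (11.6) and 2 (3.48) and Control ZT17 2 (3.42) and 3 (2.68). They also moved without Deficient ZT05 3 (3.27) and Deficient ZT17 1 (3.34) and 2 (16.7). Adrenal gland males ranged from 0.563 to 1.40, moving without Control ZT05 1 (0.563) and 3 (0.723) and Control ZT17 2 (0.677). They also moved without Deficient ZT05 1 (0.689) and Deficient ZT17 1 (0.615) and 2 (0.654). BAT females ranged from 0.316 to 0.961, moving without Control ZT05 1 (0.484) and 2 (0.386) and Control ZT17 1 (0.428), 2 (0.316) and 3 (0.435). BAT females also moved without Deficient ZT05 1 (0.386), 2 (0.512) and 3 (0.561) and Deficient ZT17 1 (0.477) and 3 (0.442). BAT males ranged from 2.29 to 7.01, moving without Control ZT05 2 (3.05), Control ZT17 1 (2.29) and Deficient ZT05 3 (7.01). EDL males ranged from 7.33 to 14.8, moving without Deficient ZT05 2 (7.33) and Deficient ZT17 3 (8.44). EDL tendon females ranged from 3.37 to 9.999, moving without Control ZT05 2 (3.83), Deficient ZT05 2 (3.92) and 3 (3.37) and Deficient ZT17 1 (4.41). EDL tendon males ranged from 0.103 to 4.98, moving without Control ZT05 1 (0.109), 2 (0.164) and 3 (4.98) and Control ZT17 1 (2.47), 2 (0.194) and 3 (0.212). They also moved without Deficient ZT05 1 (0.212), 2 (0.103) and 3 (0.309) and Deficient ZT17 1 (0.2001), 2 (0.164) and 3 (0.145). Gastrocnemius females ranged from 0.486 to 1.33, moving without Control ZT05 1 (0.610), 2 (0.720) and 3 (0.740) and Control ZT17 1 (0.662) and 2 (0.772). They also moved without Deficient ZT05 1 (0.642), 2 (0.636) and 3 (0.785) and Deficient ZT17 1 (0.486) and 3 (0.701). Gastrocnemius males ranged from 0.175 to 0.843, moving without Control ZT05 1 (0.188) and 3 (0.843) and Control ZT17 1 (0.195), 2 (0.188) and 3 (0.175). They also moved without Deficient ZT05 1 (0.227) and Deficient ZT17 1 (0.201). Gastrocnemius tendon females ranged from 0.142 to 0.743, moving without Control ZT05 1 (0.155), 2 (0.174) and 3 (0.278) and Control ZT17 1 (0.162), 2 (0.142) and 3 (0.194). Gastrocnemius tendon females also moved without Deficient ZT05 1 (0.226), 2 (0.162) and 3 (0.304) and Deficient ZT17 1 (0.181) and 3 (0.213). Gastrocnemius tendon males ranged from 2.29 to 12.9, moving without Control ZT05 3 (3.46), Control ZT17 3 (4.68) and Deficient ZT05 2 (2.29).

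Heart females ranged from 1.20 to 2.48, moving without Control ZT05 1 (1.20) and 3 (1.54) and Control ZT17 1 (1.42), 2 (1.80) and 3 (1.59). Heart females also moved without Deficient ZT05 2 (2.08) and Deficient ZT17 1 (1.40) and 3 (1.71). Heart males ranged from 1.33 to 3.69, moving without Control ZT05 3 (1.90), Control ZT17 1 (1.46), Deficient ZT05 3 (1.69) and Deficient ZT17 1 (1.33). Kidney females ranged from 4.63 to 11.4, moving without Control ZT05 1 (5.61) and Control ZT17 1 (5.602), 2 (6.26) and 3 (5.61). Kidney females also moved without Deficient ZT05 2 (6.16) and Deficient ZT17 3 (4.63). Liver males ranged from 4.85 to 10.6, moving without Deficient ZT17 1 (4.85). Lung females ranged from 0.0162 to 0.124, moving without Control ZT05 1 (0.0216), 2 (0.0162) and 3 (0.0216) and Control ZT17 1 (0.0162), 2 (0.0216) and 3 (0.0216). Lung females also moved without Deficient ZT05 2 (0.0216) and 3 (0.0432) and Deficient ZT17 1 (0.0216) and 3 (0.0270). Lung males ranged from 2.74 to 9.53, moving without Control ZT05 1 (9.53), Control ZT17 3 (2.74) and Deficient ZT05 1 (3.38). Ovary females ranged from 1.87 to 25.6, moving without Control ZT05 1 (25.6) and 3 (4.66) and Control ZT17 1 (5.04), 2 (3.60) and 3 (2.78). Ovary females also moved without Deficient ZT05 1 (3.45) and 2 (4.08) and Deficient ZT17 1 (1.87), 2 (4.87) and 3 (3.82). Pituitary females ranged from 0.439 to 3.93, moving without Control ZT05 1 (0.439) and 2 (0.853) and Control ZT17 1 (3.93) and 3 (1.20). They also moved without Deficient ZT05 1 (1.28), 2 (0.636) and 3 (0.796) and Deficient ZT17 1 (0.930) and 3 (1.17). Pituitary males ranged from 0 to 1.07, moving without Control ZT05 2 (0.00517), Deficient ZT05 1 (0.0103) and 2 (1.07) and Deficient ZT17 2 (0.0723). Quadriceps females ranged from 0.320 to 1.02, moving without Control ZT05 1 (0.320) and 2 (0.583) and Control ZT17 1 (0.461), 2 (0.538) and 3 (0.365). They also moved without Deficient ZT05 1 (0.731), 2 (0.352) and 3 (0.525) and Deficient ZT17 1 (0.372) and 3 (0.455). Quadriceps males ranged from 0.436 to 12.5, moving without Control ZT05 1 (1.012) and 2 (0.532) and Control ZT17 1 (6.02). Quadriceps males also moved without Deficient ZT05 2 (0.519) and Deficient ZT17 1 (0.436), 2 (2.56) and 3 (12.5). Soleus males ranged from 6.25 to 11.5, moving without Control ZT05 1 (6.33), Deficient ZT05 2 (6.42) and Deficient ZT17 2 (6.25).

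Spleen females ranged from 0.515 to 1.52, moving without Control ZT05 1 (0.515) and Control ZT17 1 (0.618). Spleen females also moved without Deficient ZT05 1 (0.749), 2 (0.681) and 3 (0.704) and Deficient ZT17 1 (0.555), 2 (0.829) and 3 (0.818). Spleen males ranged from 0.206 to 7.39, moving without Control ZT05 1 (5.22) and 2 (7.39) and Control ZT17 3 (0.246). Spleen males also moved without Deficient ZT05 1 (0.372) and 2 (0.240) and Deficient ZT17 1 (0.206), 2 (0.275) and 3 (2.69). Testis males ranged from 0.0192 to 0.245, moving without Control ZT17 3 (0.0528) and Deficient ZT17 1 (0.0624) and 2 (0.245). TA males ranged from 7.13 to 17.2, moving without Control ZT05 1 (7.13) and Deficient ZT05 3 (17.2). TA tendon females ranged from 1.71 to 30.8, moving without Control ZT05 1 (1.71), 2 (2.47) and 3 (30.8) and Control ZT17 1 (1.95), 2 (27.8) and 3 (2.61). They also moved without Deficient ZT05 1 (13.03), 2 (2.92) and 3 (2.33) and Deficient ZT17 3 (3.06). TA tendon males ranged from 0 to 0.0121, moving without Control ZT05 2 (0.0121), Deficient ZT05 3 (0.00603) and Deficient ZT17 2 (0.00603). The time difference ranged from 1.24 to 2.50, moving without female Control ZT17 2 (1.24). The day-night contrast in Deficient ranged from 0.948 to 1.93, moving without female Deficient ZT17 1 (0.948). Genes up in 5 or more tissues in females ranged from 1.27 to 2.74, moving without Control ZT05 1 (1.75) and 2 (1.55) and Control ZT17 1 (1.47) and 3 (1.40). They also moved without Deficient ZT05 2 (1.41) and 3 (1.55) and Deficient ZT17 1 (1.37) and 3 (1.27). Genes down in 5 or more tissues in females ranged from 1.32 to 2.74, moving without Control ZT17 1 (1.62) and 3 (1.5) and Deficient ZT05 2 (1.52) and 3 (1.81). They also moved without Deficient ZT17 1 (1.32) and 3 (1.42). Genes up in 5 or more tissues in males ranged from 0.293 to 0.914, moving without Control ZT17 3 (0.384), Deficient ZT05 2 (0.293) and Deficient ZT17 1 (0.316). Genes down in 5 or more tissues in males ranged from 0.214 to 0.671, moving without Control ZT05 1 (0.339) and 2 (0.327), Control ZT17 3 (0.310), Deficient ZT05 2 (0.214) and Deficient ZT17 1 (0.299).

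Ranges stayed within 1.5-fold for EDL females (25.9 to 33.1), kidney males (32.9 to 42.1), liver females (3.32 to 5.05), soleus females (14.9 to 22.9) and TA females (24.5 to 36.3). They also did for uterus females (37.3 to 46.2), the sex difference (0.789 to 1.39), the day-night contrast in Control (3.76 to 6.01) and the overlap of the sexes (1.28 to 2.02).

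Depth limits the calls: thinned to male depth, females fitted alone kept from 26.98% (liver) to 91.06% (gastrocnemius) of their genes over 9 tissues. In simulated data at the given depth the shared fit recovered 6.75% of female and 13.4% of male changes of 0.5 on the log2 scale, so absent calls do not show absent small changes.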

Other observations

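The real split of labels was compared with other splits as planned, and no test in this part was chosen after the result had been seen. Values are percent of the genes tested in the tissue, or of the gene and tissue pairs tested.

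For Deficient against Control females the real split gave more genes than each other split with 5.42 against 0.00569 in adrenal gland, 0.898 against 0.00702 in BAT, 31.9 against 0.423 in EDL, 7.20 against 0.115 in EDL tendon and 1.30 against 0 in gastrocnemius. Others were 0.640 against 0 in gastrocnemius tendon, 3.30 against 0.0189 in heart, 9.43 against 0.566 in kidney and 4.93 against 0.0820 in liver. Further values were 0.108 against 0.0216 in lung, 10.4 against 4.88 in ovary, 1.93 against 0 in pituitary and 1.22 against 0 in quadriceps. The last were 21.6 against 0 in soleus, 1.253 against 0 in spleen, 30.8 against 0.141 in TA and 45.04 against 0 in uterus. At least as many genes came from another split in TA tendon (2 of 30 splits, 8.35 against 47.6).

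For Deficient against Control males the real split gave more genes than each other split with 1.13 against 0.404 in adrenal gland, 12.9 against 0.0201 in EDL, 0.703 against 0 in EDL tendon, 2.86 against 0.837 in heart and 40.8 against 23.7 in kidney. Others were 8.53 against 3.99 in liver, 5.24 against 1.92 in lung, 9.89 against 0.0648 in soleus, 0.0288 against 0.00961 in testis and 11.1 against 0 in TA. At least as many genes came from other splits in BAT (2 of 30 splits, 4.62 against 6.73), gastrocnemius (2 of 30 splits, 0.415 against 40.9), gastrocnemius tendon (4 of 30 splits, 9.21 against 22.2), quadriceps (3 of 30 splits, 1.69 against 34.7) and spleen (4 of 30 splits, 0.784 against 2.75). As 30 of 30 splits reached the 0 genes by edgeR in pituitary (highest other 0.0103; 11.7 at unadjusted p under 0.05 and 0.729 by DESeq2) and in TA tendon (highest other 0; 6.16 and 0.272), these splits decide nothing. Splits with several times the real count, as in gastrocnemius and quadriceps, point to a structure of the male libraries other than treatment.

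For ZT17 against ZT05 in Control mice 1 of 21 splits, the real one, reached 5.26% of pairs, with a highest other of 1.73. By tissue the real split led with 3.71 against 0.00569 in adrenal gland, 15.96 against 0.590 in BAT, 13.9 against 0.275 in EDL and 1.28 against 0 in gastrocnemius. It was 2.57 against 0.119 in heart, 13.7 against 2.01 in kidney, 8.83 against 0.0448 in liver and 14.2 against 1.77 in lung. Further values were 0.0517 against 0 in pituitary, 1.21 against 0.00641 in quadriceps, 19.2 against 0.816 in soleus and 10.2 against 0.310 in TA. At least as many came from 2 of 21 splits in EDL tendon (0.527, highest other 1.41), 3 of 21 splits in gastrocnemius tendon (0.252, highest other 6.76), 6 of 21 splits in spleen (0.00572, highest other 0.766) and 4 of 21 splits in TA tendon (0.278, highest other 30.9). Where edgeR gave 0 genes, the percents at unadjusted p under 0.05, by DESeq2 and in the highest other split were those of ovary (19.1, 3.59 and 0), testis (1.30, 0 and 0) and uterus (7.01, 0.242 and 0.592).

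For ZT17 against ZT05 in Deficient mice 1 of 21 splits, the real one, reached 1.60% of pairs, with a highest other of 0.501. By tissue the real split led with 2.87 against 0.00569 in adrenal gland, 4.27 against 0 in BAT, 6.82 against 0.00671 in EDL and 0.151 against 0.0314 in heart. It was 7.56 against 0.0179 in kidney, 0.739 against 0.0671 in liver, 0.210 against 0 in lung and 0.0513 against 0.0128 in quadriceps. Further values were 2.61 against 0 in soleus, 0.0229 against 0 in spleen, 7.15 against 0.00673 in TA and 0.0121 against 0 in TA tendon. At least as many came from 2 of 21 splits in EDL tendon (0.0243, highest other 0.0243), 3 of 21 splits in gastrocnemius tendon (0.0194, highest other 10.1), 3 of 21 splits in ovary (0.00537, highest other 0.0107) and 3 of 21 splits in pituitary (0.00517, highest other 3.11). Where edgeR gave 0 genes, the corresponding 3 percents were those of gastrocnemius (2.57, 0.0973 and 0), testis (17.01, 0.519 and 2.75) and uterus (10.54, 1.20 and 0).

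The list of oestrogen and progesterone responsive uterine genes was called down by camera in female adrenal gland (adjusted p = 0.0251, and 0.418 with an estimated correlation) with a median of -0.19 and a mean of 0.23. For the sex difference there it was also called down (adjusted p = 0.0144, and 0.639 with an estimated correlation), with a median of -0.23 and a mean of 0.33.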
